A study of Dictyostelium discoideum with 8 samples.

How the data were processed

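Total RNA from 8 cultures of AX3 amebae (4 WT, 4 ttpA-D450trx) was made into libraries from 250 ng each with an Illumina TruSeq RNA kit and 12 PCR cycles, per the labels' protocols. The authors deposited raw counts per gene, whole numbers with a different total in every library, and a second table of normalized signal. Per the submitters' processing notes the tools were bcl2fastq, STAR 2.6.0c and featureCounts 1.5.1. The genome build, annotation, strand setting and treatment of reads that map to several places are not given in the sources used here, so overlapping and antisense genes, and near-identical copies, could not be told apart by their reads. The deposited normalized signal was the raw count divided by 1 factor per library (from 1.34 to 2.60). These factors were 2.07 to 2.12 times the DESeq2 size factors of the 8 libraries. The normalized table was used only for this check.

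Totals ran from 81528750 to 141975423 counts per library. The table held 12865 genes, of which 509 had no count in any library. Libraries were grouped by the genotype in the labels. Each library was counted as a replicate because the labels describe separate cultures. No within-group pair of libraries agreed within sampling noise, as 1 library deposited more than once would (chi-square per degree of freedom from 5.76 to 94.2). Replicate numbers are shared between the groups; the labels tie no numbers together, and the deviations of same-numbered libraries did not correlate, so the libraries were not treated as pairs.

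Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by group, glmQLFit and glmQLFTest, no covariate), with Benjamini-Hochberg adjustment over 10653 genes and a threshold of 0.05. CPM were computed with TMM-scaled library sizes. The standard error of a log2 fold change was taken as its absolute value over the square root of the F statistic. The common biological coefficient of variation was 0.0826. Intervals for counts pooled over the 4 libraries of a group cover counting error only and leave out variation between cultures. The reads also carry no molecular identifiers.

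Before the data were examined, 33 gene lists were fixed by patterns on gene symbols, and 32 with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry. For each list the numbers of higher and lower genes were counted after adjustment over all genes and over the list alone. The rule for named genes was fixed at the same time. It took, among genes past the threshold with all libraries of one group above all of the other, the 12 largest rises and 12 largest falls with a mean of at least 5 CPM in the higher group, and up to 3 members of each list with the smallest p. Genes named outside it were chosen after their values were seen. These are efaAI, sgkA, oxct, kif5, kif7, vatD-1, vatD-2, vatA_ps, DDB_G0267236_RTE and DDB_G0267346 at the ends of a run, and the genes of the stretch other than gtaC and amtA. The members of symbol families and neighbouring genes that the closing observations name were chosen in the same way.

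Gene order came from RefSeq's annotation of dicty_2.7, an assembly that may differ from the one used for counting, and served only to find neighbours: 12728 identifiers matched, and 10555 tested genes had a place. The largest median over 25 consecutive tested genes was compared with 1000 permutations of gene order. The stretch of lower genes was defined after the data were seen, by growing the lowest window of 25 genes, transposable-element genes and pseudogenes left out, while the median of its 5 outermost genes stayed at or below -0.5.

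The procedures were tested on simulated data built from these libraries' means and dispersions. For the comparison of 4 mutant with 4 WT libraries over 10604 genes, 50% of genes changed 1.25-fold were recovered, 66% of those changed 1.5-fold, 89.8% of those changed 2-fold and 100% of those changed 4-fold, and 6.75% of all calls were false. Only 49 or 50 genes were changed at each of these sizes, and 10405 were unchanged. In the data 38.3% of the tested genes were called, so recovery and the share of false calls may differ there. The window search placed its 25 genes inside a simulated stretch of 30. The list test called the 1 shifted list and 0 of the others. Each gene was simulated independently, so this does not show how often unshifted lists are called when their genes vary together.

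The alternatives were DESeq2 size factors, upper-quartile factors, no low-count filter, at least 10 counts in all 8 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a test against a 1.5-fold change, windows of 10 and 50 genes, and leaving out each library in turn. Leaving out transposable-element genes and pseudogenes, and leaving out the stretch of lower genes, were added after the data were seen. Expression of ttpA and sequence motifs downstream of genes were planned and not analysed here. Figures were drawn with matplotlib 3.10.9.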

Results

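RNA was sequenced from 8 axenic cultures of Dictyostelium discoideum, a social ameba that grows as single cells and aggregates into a multicellular body when starved. All cultures were of strain AX3, a laboratory line that grows in liquid medium without bacteria, and were frozen at about 80% confluence. Of these, 4 were wild type (WT) and 4 carried ttpA-D450trx, an altered form of ttpA, the gene of a tristetraprolin-family protein. Proteins of this family bind messenger RNAs through zinc fingers and promote their decay. The labels describe the libraries as separate cultures, and they do not say how many mutant clones were used. Total counts per library ranged from 110070697 to 138948484 in WT and from 81528750 to 141975423 in the mutant. The totals did not differ between the groups by a two-sided exact permutation test (p = 0.543 over 70 arrangements). The most abundant gene, efaAI, took between 1.20% and 1.48% of the counts of a library. Expression of ttpA itself was not analysed here, so the genotypes were taken from the labels. The first principal component of log-transformed CPM (counts scaled to library size) held 73.8% of the variance and separated the 4 mutant from the 4 WT libraries. The second held 8.98%, and on it mutant replicate 3, the library with the lowest total count, lay farthest from the others.

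The single comparison asked which transcripts differ in level between mutant and WT cultures. The mutant had far more transcript of the small GTPase gene rasD (DDB_G0292996), of the superoxide dismutase gene sodC (DDB_G0282993), of the cysteine protease gene cprF (DDB_G0279185) and of a group of transposable-element genes. It had far less of uduC (DDB_G0270726), of cafA (DDB_G0277827), which encodes the calcium-binding protein calfumirin, of the calcium-binding protein gene cbpG (DDB_G0283609), and of the early-development genes acaA and csaA. Of 10653 tested genes, 2108 were higher and 1971 lower in the mutant by edgeR's quasi-likelihood test at an adjusted p under 0.05, together 38.3% of the tested genes. Most of these shifts were small, with a median absolute log2 fold change of 0.31 among the 4079 genes. A change of at least 2-fold was met by 296 genes that were higher and 230 that were lower. When the null hypothesis was a change of up to 1.5-fold, 282 genes were higher and 236 lower.

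**Figure D1:**
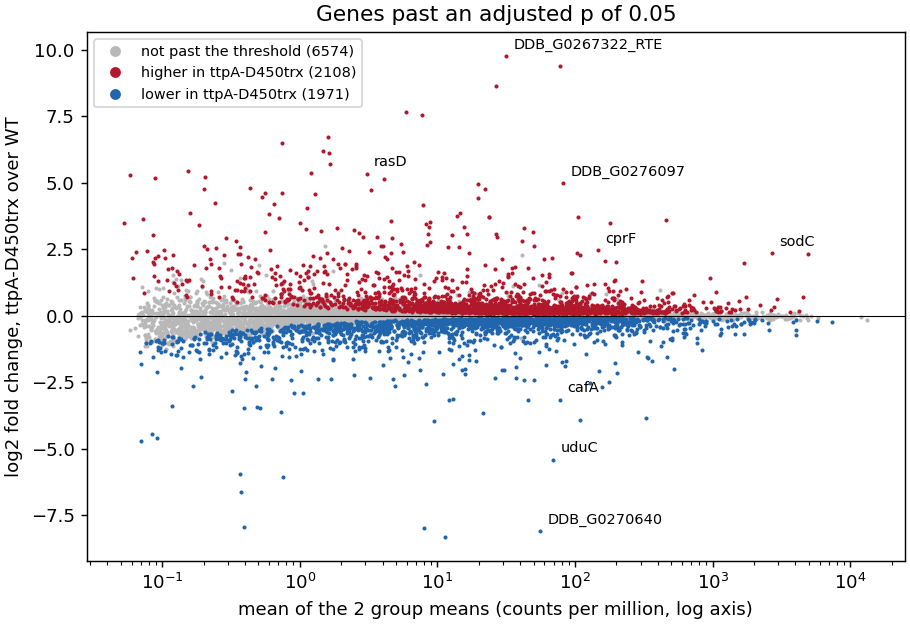
Log2 fold change of each tested gene, mutant over WT, against the mean of the group means in CPM on a log axis. Each point is 1 gene, in red for the 2108 genes higher and in blue for the 1971 genes lower at an adjusted p under 0.05; most coloured points lie close to 0, with a sparse set of far larger changes on both sides.

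Among genes outside the transposable elements, rasD had the largest rise under the naming rule, from 0.146 CPM ± 0.0488 (SD, n = 4) in WT to 5.96 CPM ± 2.23 (SD, n = 4) in the mutant (log2 fold change 5.34 ± 0.34 SE; edgeR adjusted p = 1.9e-06). The uncharacterized gene DDB_G0276097 rose from 5.01 CPM ± 0.825 to 159 CPM ± 37.9 (SD, n = 4 each), and its nearest tested neighbour DDB_G0276219 rose from 1.58 CPM ± 0.219 to 43.0 CPM ± 8.96 (SD, n = 4 each). DDB_G0275487, DDB_G0280501 and DDB_G0276671 rose by 30.9-fold, 26.6-fold and 21.5-fold. Of the abundant transcripts, sodC rose 5.15-fold, from 879 CPM ± 8.71 to 4523 CPM ± 405 (SD, n = 4 each; edgeR adjusted p = 4.5e-09). The remaining 6 of the 12 largest rises were transposable-element genes, described with their class.

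The 3 largest falls were in genes that were almost without counts in the mutant. DDB_G0270640 fell from 111 CPM ± 1.16 to 0.398 CPM ± 0.0317 (SD, n = 4 each), a log2 change of -8.12 ± 0.05 SE (edgeR adjusted p = 4.0e-14). DDB_G0276925 fell from 22.6 CPM ± 0.734 to 0.0670 CPM ± 0.0228, and DDB_G0293166 from 16.0 CPM ± 1.69 to 0.0639 CPM ± 0.0146 (SD, n = 4 each). The gene uduC was 42.7-fold lower, at 136 CPM ± 6.53 in WT and 3.21 CPM ± 0.746 in the mutant (SD, n = 4 each; edgeR adjusted p = 3.4e-09). DDB_G0276969 fell from 610 CPM ± 8.68 to 42.6 CPM ± 4.63, and cafA from 140 CPM ± 6.94 to 15.7 CPM ± 3.16 (SD, n = 4 each). DDB_G0279951, DDB_G0288123, lmcA, DDB_G0284619, prtA and cbpG were between 8.72-fold and 15.5-fold lower.

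**Figure D2:**
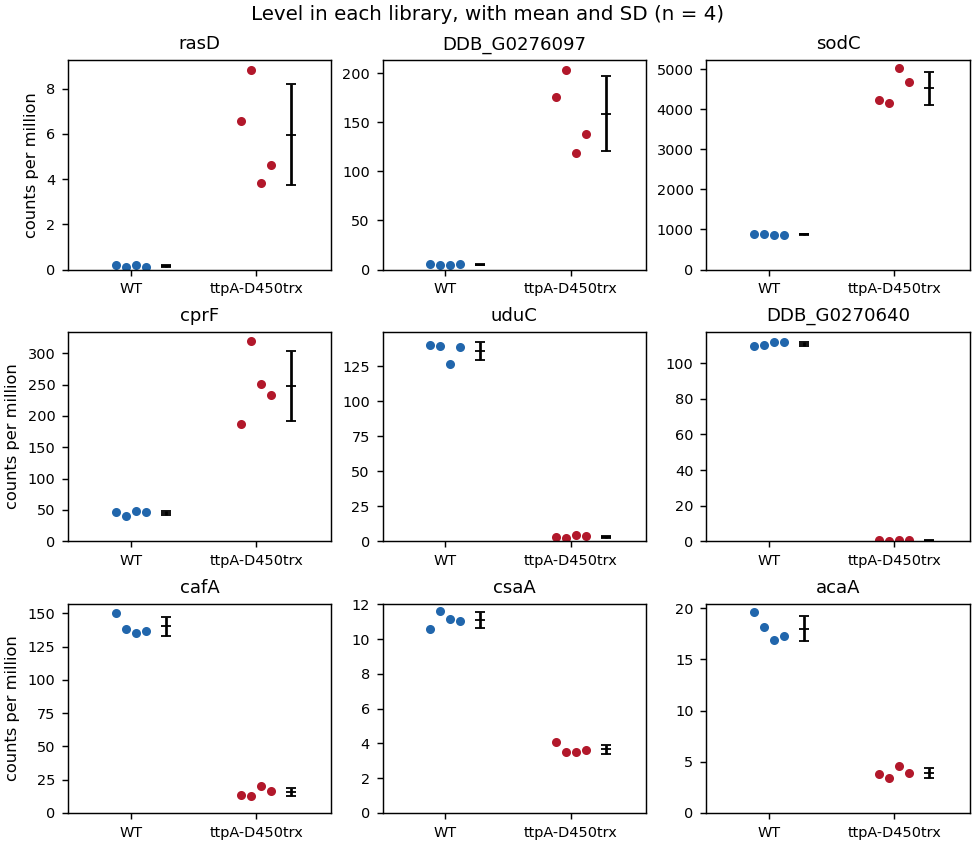
CPM of 9 named genes in each library, on linear axes that start at 0. Points are the 4 WT libraries (blue) and the 4 mutant libraries (red), and bars give the mean ± SD (n = 4); in each panel all 4 libraries of a group lie apart from all 4 of the other.

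Genes of cAMP signalling and cell adhesion that are used during aggregation were mostly lower in the mutant. Of 21 tested members, 16 were lower, 5 of them at least 2-fold, 1 (sgkA) was higher and 4 did not pass the test, and adjusted over the list alone 17 were lower and 1 higher. The aggregation-stage adenylyl cyclase gene acaA (DDB_G0281545) fell from 18.0 CPM ± 1.22 to 3.92 CPM ± 0.487 (SD, n = 4 each), and csaA (DDB_G0289073), the gene of the contact site A adhesion protein, from 11.1 CPM ± 0.443 to 3.68 CPM ± 0.258 (SD, n = 4 each; edgeR adjusted p = 6.9e-08 for both). The gene of the phosphodiesterase inhibitor, pdiA (DDB_G0277863), was 3.39-fold lower, and gtaC (DDB_G0277589), which encodes a GATA-type transcription factor of early development, 2.00-fold lower, from 60.01 CPM ± 2.42 to 29.96 CPM ± 1.255 (SD, n = 4 each). The median log2 fold change of the list was -0.26. As a set it was lower than other genes by camera with a preset correlation (adjusted p = 2.4e-11), and not past the threshold with an estimated correlation (adjusted p = 0.128).

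Among genes for DNA replication and for mitosis more were lower than higher, by small amounts. Of 35 tested replication genes, 21 were lower, 0 higher and 14 not past the threshold, with the same 21 and 0 when adjusted over the list alone, and a median log2 fold change of -0.22. No replication gene was higher at an unadjusted edgeR p under 0.05 either (0, against 24 lower), nor with DESeq2 (0, against 22 lower). In this list mcm2, a subunit of the replicative helicase, had a log2 fold change of -0.34 ± 0.05 SE. Of 54 genes of mitosis and cytokinesis, 22 were lower, 2 higher (the kinesin genes kif5 and kif7) and 30 not past the threshold (25 lower and 2 higher adjusted over the list alone); the lower ones included the cyclin genes cycA (log2 fold change -0.57) and cycB (-0.50). Camera gave an adjusted p of 0.0028 for replication and 0.038 for mitosis; with an estimated correlation the adjusted p was 0.993 for both. The mitosis list was not past the threshold without WT replicate 2 (adjusted p = 0.057) or without mutant replicate 3 (adjusted p = 0.050).

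Cytochrome P450 genes, sterol and lipid enzymes and transcription factors also had more lower than higher members. Among 35 P450 genes, 15 were lower and 3 higher (18 and 3 adjusted over the list alone), with cyp513F1 6.28-fold, cyp508A4 4.15-fold and cyp519E1 2.64-fold lower. Among 20 sterol and lipid genes, 9 were lower and 1 higher, also adjusted over the list alone, including erg24, which fell from 2092 CPM ± 51.8 to 1286 CPM ± 94.2 (SD, n = 4 each). Among 85 transcription factor genes, 37 were lower and 10 higher (38 and 12 adjusted over the list alone), with gtaQ 1.87-fold and gtaT 1.46-fold lower. The camera adjusted p was 0.0020 for P450 genes, 0.048 for sterol and lipid genes and 0.011 for transcription factors. With an estimated correlation the adjusted p was 0.622, 0.770 and 0.622. The sterol and lipid call was also lost with DESeq2 size factors (adjusted p = 0.052) and without any 1 of WT replicates 1, 2 and 3 or mutant replicate 2 (adjusted p from 0.056 to 0.082).

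Subunits of the V-ATPase, the proton pump of endosomes and the contractile vacuole, were mostly higher, by small amounts. Of 12 tested, 9 were higher and 0 lower, also adjusted over the list alone, with a median log2 fold change of 0.22. The gene vatH rose by 0.31 ± 0.04 SE on the log2 scale. Not past the threshold were vatD-1, vatD-2 and the pseudogene vatA_ps, weakly counted at 0.403, 0.461 and 0.0885 CPM in WT. At an unadjusted edgeR p under 0.05, and with DESeq2, the numbers were again 9 and 0. The camera adjusted p was 0.039. It was 0.993 with an estimated correlation, and between 0.051 and 0.070 without WT replicate 1, WT replicate 2 or mutant replicate 2.

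**Figure D3:**
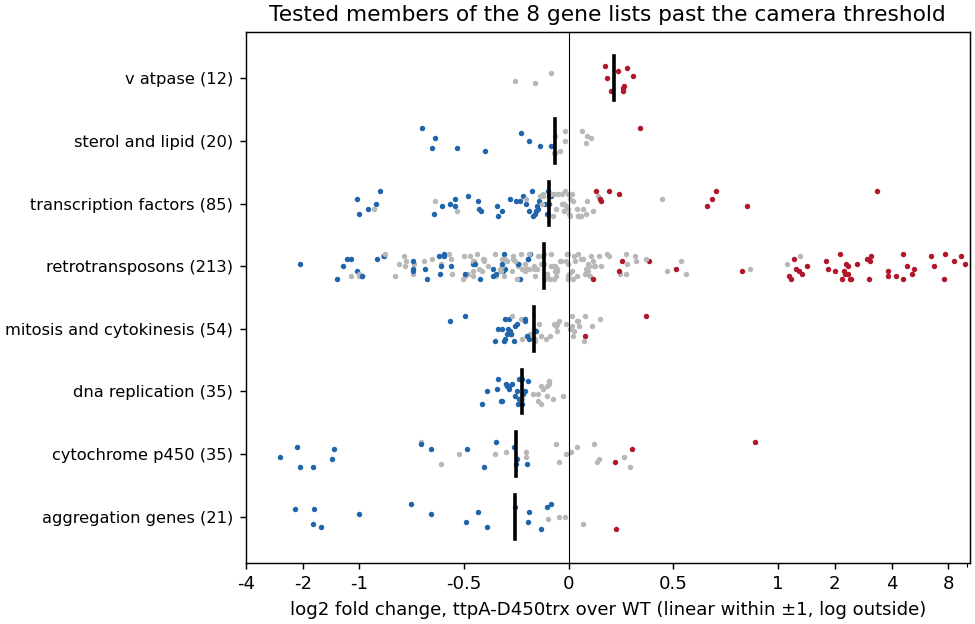
Log2 fold change, mutant over WT, of each tested member of the 8 gene lists past the camera threshold with a preset correlation; the axis is linear within ±1 and logarithmic outside, and the number of tested members follows each name. Points are genes, red for higher, blue for lower and grey for not past the threshold, and the bar is the list's median, lowest for aggregation genes (-0.26) and highest for the V-ATPase (0.22).

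Transposable-element genes moved both ways. Of 213 tested, 45 were higher, 37 lower and 131 not past the threshold (45 and 38 adjusted over the list alone), and 39 of the higher ones rose at least 2-fold. DDB_G0267322_RTE rose from 0.0742 CPM ± 0.0297 to 63.3 CPM ± 6.60, and DDB_G0267328_RTE from 0.229 CPM ± 0.0420 to 156 CPM ± 21.2 (SD, n = 4 each; log2 fold changes 9.76 ± 0.14 SE and 9.39 ± 0.14 SE). DDB_G0291221_RTE, DDB_G0267188_RTE and DDB_G0291217_RTE rose by 8.62, 7.68 and 7.56 on the log2 scale. These sequences exist in many near-identical copies, so which copy a read came from is uncertain. The median of the class was -0.12 and its mean 0.46 on the log2 scale, and the camera test gave a higher set (adjusted p = 0.032). That call was lost with an estimated correlation (adjusted p = 0.520), without mutant replicate 1 (adjusted p = 0.342) and without mutant replicate 4 (adjusted p = 0.157).

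None of the remaining lists was past the threshold by camera, which compares a list with the other genes. Fry asks instead whether the genes of a list are shifted on average, without that comparison. Such a test can pass for many lists where 38.3% of all tested genes were called. By fry, 10 of these 24 lists were past the threshold. The direction was up for 5, lysosomal hydrolases (adjusted p = 0.00031), endoplasmic reticulum genes (0.0048), tRNA synthetases (0.0069), ribosome biogenesis (0.010) and autophagy (0.012). It was down for the other 5, ABC transporters (0.0018), adhesion and phagocytosis (0.0028), the hssA family (0.0047), the proteasome (0.021) and G protein-coupled receptors (0.032). The 5 tested hssA genes were weakly counted, with a highest WT mean of 0.399 CPM (sigN25). Of these, 2 were lower, 0 higher and 3 not past the threshold (2 and 0 adjusted over the list alone; camera adjusted p = 0.527). Lysosomal hydrolases had 12 higher and 6 lower of 28 (14 and 6 adjusted over the list alone; camera adjusted p = 0.093), with cprF up 5.47-fold. Of 12 endoplasmic reticulum genes, 10 were higher, among them the chaperone gene grp94 (1.28-fold), and 2 were lower, the phosphodiesterase inhibitor gene pdiA and oxct (log2 fold change -0.18), neither of them a chaperone gene (10 and 2 adjusted over the list alone; camera adjusted p = 0.205). Of 21 adhesion and phagocytosis genes, 6 were higher and 8 lower (6 and 8 adjusted over the list alone; camera adjusted p = 0.205), and the adhesion protein genes csbC and csbB were 5.34-fold and 3.32-fold lower. Of 37 actin genes, 10 were higher and 9 lower (11 and 11 adjusted over the list alone; 9 higher and 10 lower with upper-quartile factors), and act25 rose 6.01-fold, in a family whose near-identical members share reads. Cytosolic ribosomal protein genes hardly moved, with 1 higher and 2 lower of 77 (0 and 0 adjusted over the list alone). Of 31 proteasome genes, 0 were higher and 11 lower (0 and 6 adjusted over the list alone; camera adjusted p = 0.181), against 0 and 17 at an unadjusted edgeR p under 0.05 and 0 and 15 with DESeq2; with upper-quartile factors 18 were lower and 0 higher. Ribosome biogenesis genes had 6 higher, 0 lower and 22 not past the threshold of 28 (4 and 0 adjusted over the list alone; camera adjusted p = 0.320), against 12 and 0 at an unadjusted edgeR p under 0.05 and 7 and 0 with DESeq2. Of 24 tRNA synthetase genes, 9 were higher, 1 lower and 14 not past the threshold (11 and 1 adjusted over the list alone; camera adjusted p = 0.205). Markers of prespore cells (3 higher, 5 lower of 14) and of prestalk cells (3 higher, 3 lower of 15), with the same numbers adjusted over the list alone, gave camera adjusted p-values of 0.835 and 0.763. Genes of mRNA decapping and decay had 2 higher and 1 lower of 16, also adjusted over the list alone (camera adjusted p = 0.939). The lower one was the pseudogene dcp2_ps. With upper-quartile factors 2 were higher and 3 lower.

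Discoidin genes encode lectins, some of which are raised late in growth as cell density rises. All 4 tested members were lower, also adjusted over the list alone. The list had too few tested members for a set test. The abundant member dscE (DDB_G0292552) fell from 727 CPM ± 13.9 to 510 CPM ± 20.99 (SD, n = 4 each; edgeR adjusted p = 3.5e-06). The others had few counts and are near-identical copies: dscA-1 had 70 counts over the 4 WT libraries and 2 over the 4 mutant libraries, a WT-to-mutant ratio of 32.0 with an exact 95% counting interval of 8.53 to 269.

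Changes were not spread evenly over the gene order. With tested genes placed by the RefSeq annotation of assembly dicty_2.7, the largest median of 25 consecutive genes was a log2 fold change of 2.97, in a run rich in transposable-element genes from DDB_G0267236_RTE to DDB_G0267346. In 1000 permutations of the gene order the largest was 0.50 (p = 0.001, the smallest they can give). The lowest median, -0.98, lay in ordinary genes ending at gtaC. Extended outward from that window, a stretch of 36 tested genes from DDB_G0277525 to DDB_G0277639 had 35 lower and 0 higher, with a median log2 fold change of -0.91 (interquartile range -1.05 to -0.80), or 0.533-fold. It includes capB, which fell from 579 CPM ± 27.4 to 292 CPM ± 4.65 (SD, n = 4 each), the GTPase gene rabJ (log2 fold change -0.87), the ammonium transporter gene amtA (-0.60), the dynactin gene dynC (-0.93), gtaC (-1.003) and gtaH (-0.48). The 50 flanking tested genes, 25 on each side, had a median of 0.04, with 12 lower, 7 higher and the others not past the threshold.

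**Figure D4:**
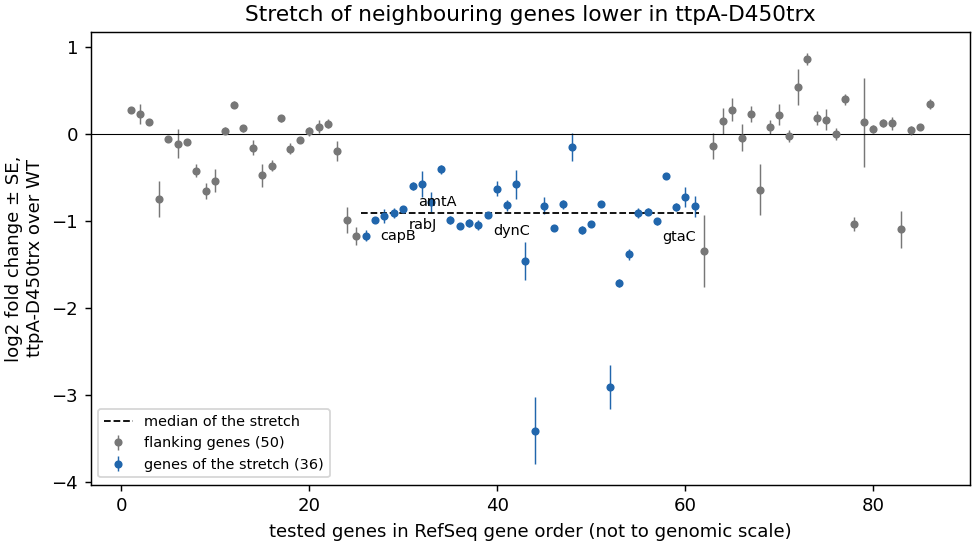
Log2 fold change ± SE, mutant over WT, of the 36 tested genes of the stretch (blue) and the 50 flanking tested genes (grey), placed by their order in the RefSeq annotation and not to genomic scale. The dashed line is the median of the stretch, -0.91; the flanking genes scatter around 0, with 12 of the 50 lower at an adjusted p under 0.05, 3 of them transposable-element genes or a pseudogene next to its ends and 9 other genes, and 7 higher.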

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

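The flags below come from a fixed rule for single libraries, and the tests over other groupings of the libraries were set down only after the results were seen. A library was noted where its gap to the nearest other library of its group, as a share of the group's range, exceeded Dixon's 95% critical value for 4 samples. Of 242 sets of 4 libraries examined, 11 were noted, and chance notes about 1 in 20, or 12.1.

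In the mutant group, replicate 3 stood apart for DDB_G0267328_RTE (ratio 0.837; 187 CPM against 141 to 149 in the others), for cbpG (0.927; 2.12 against 2.77 to 2.83 CPM), for mrpl21 (0.929; 57.4 against 55.4 to 55.5 CPM) and for cyp508A4 (0.939; 17.0 against 10.02 to 10.4 CPM). Mutant replicate 1 stood apart for DDB_G0276925 (0.852; 0.101 against 0.0513 to 0.0586 CPM) and csaA (0.831; 4.06 against 3.51 to 3.61 CPM). In WT, replicate 3 stood apart for uduC (0.928; 126 against 139 to 140 CPM), dstA (0.957; 198 against 191 CPM), vatM (0.859; 981 against 938 to 944 CPM) and mcm2 (0.860; 52.9 against 49.9 to 50.3 CPM), and replicate 1 for sigN1 (0.899; 0.125 against 0.179 to 0.185 CPM).

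The libraries can be divided into groups of 4 and 4 in 35 ways. Only 1 of the 35, the real one, gave as many genes past the threshold (4079, against 0 in each of the other groupings). The same held for genes with a 2-fold change (526, against 0). Each other grouping mixes WT with mutant libraries, so the difference between WT and mutant widens the spread within its groups and makes calls unlikely. Ranking first, 1 of 35, is also the smallest share the groupings can give, and several patterns were tried, so it does not exclude chance. At an unadjusted edgeR p under 0.05 the other groupings gave between 36 and 1167 genes, against 5052; DESeq2 was not run on them. The real grouping also ranked first for the largest median of 25 consecutive genes (2.97, highest other 1.39). It ranked first for the camera p of the aggregation genes (7.6e-13, smallest other 6.5e-07) and narrowly for that of the transposable-element genes (0.0051, smallest other 0.0077). The real grouping did not rank first for the camera p of the other 6 lists past the threshold. As small a p came in 23 of 35 groupings for DNA replication (0.00026, smallest other 1.4e-15), 22 for mitosis (0.0072, smallest other 5.0e-10), 10 for the V-ATPase (0.0085, smallest other 1.2e-06), 7 for transcription factors (0.0014, smallest other 2.3e-05), 6 for P450 genes (0.00013, smallest other 1.8e-06) and 5 for sterol and lipid genes (0.012, smallest other 0.00055). By the absolute median log2 fold change of a list, the real grouping ranked first for 5 of these 6. These were DNA replication (0.222, highest other 0.173), mitosis (0.165, highest other 0.146), the V-ATPase (0.217, highest other 0.172), P450 genes (0.254, highest other 0.182) and transcription factors (0.096, highest other 0.067). It also ranked first for aggregation genes (0.257, highest other 0.199). The same held for some, not all, of the lists not past the camera threshold, among them prespore genes (0.116, highest other 0.093) and the proteasome (0.073, highest other 0.064). A first rank on this median therefore does not set the called lists apart. The transposable-element median ranked first too (0.117, highest other 0.076), but that median was negative (-0.117) and so gives no support to the camera call of a higher set. The sterol and lipid median did not rank first, as 5 of 35 groupings were as large (0.067, highest other 0.114). Nor did the real grouping stand out by the number of gene lists past the threshold: 16 of 35 groupings gave at least 8, and the highest other gave 15.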

How the results depend on the processing

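The counts of genes past the threshold (4079) and of genes with a 2-fold change (526), in both directions, stayed within 1.5 times the reported value under each alternative run; those that left out transposable-element genes and pseudogenes, or the stretch of lower genes, were chosen after seeing the data. The first count ran from 3366 (without WT replicate 2) to 4338 (without mutant replicate 3), and the second from 404 (at least 10 counts in all 8 libraries) to 587 (no low-count filter). No gene called in both the reported fit and a refit changed direction. Under upper-quartile factors 45.4% of calls were higher, against 51.7%. With the replicate number as a block there were 3413 calls; same-numbered libraries had correlations of -0.065, 0.0040, -0.0094 and -0.18, so the numbers did not pair the libraries. The number of gene lists past the threshold was the least stable value. It fell from 8 to 0 with an estimated correlation, and ran from 5 (without WT replicate 2) to 11 (without mutant replicate 1) when 1 library was left out; the cause was not tested. The largest median of 25 consecutive genes, 2.97, ran from 2.30 to 3.03 when 1 library was left out, and was 1.23 over 50 genes and 4.98 over 10. Without transposable-element genes and pseudogenes the largest was -0.98, because the run with the highest median held 22 such genes among its 25 and the stretch near gtaC then led. Of the named genes, dcp2_ps, rpl22a, rps14, rpa5 and sigN1 lost significance in at least 1 refit, with their direction kept. In the simulation, which changed far fewer genes than were called here, the smallest changes were recovered in 50% of cases. Smaller shifts are reported with less certainty. Not run were the planned tests of ttpA expression and of sequence motifs.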

Other observations

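All tests in this part were chosen after the results were seen. Symbol families (genes that share the first letters of their symbol, 152 families with at least 5 tested members) were each compared with the rest of 3023 tested genes with such symbols by one-sided Fisher's exact tests of 2-fold changes. Past the threshold were 4 families for rises (ras, rac, pon and cpr) and 3 for falls (udu, cbp and cyp). These tests count each member as independent. Members that are near-identical, such as racF1 and racF2, or neighbours, such as cbpG with cbpF and cbpC, are not. The family p-values may therefore be too small. The udu genes fell as a family: all 10 tested members were lower, 8 of them at least 2-fold (adjusted p = 1.5e-10), including uduF, from 299 CPM ± 11.3 to 52.6 CPM ± 6.32, and uduA3, from 841 CPM ± 41.8 to 209 CPM ± 52.2 (SD, n = 4 each). Of 16 cbp genes, which encode calcium-binding proteins, 8 were lower, 6 of them at least 2-fold (adjusted p = 3.3e-05), and 4 were higher. The gene cbpE fell from 47.1 CPM ± 1.69 to 11.5 CPM ± 1.05 (SD, n = 4 each). Among the 2-fold falls, cbpD2, cbpF and cbpC had WT means of only 0.827, 0.554 and 0.334 CPM. Of 34 cyp genes, mostly cytochrome P450 genes, 15 were lower, 6 of them at least 2-fold (adjusted p = 0.0028), and 4 were higher. Among these 2-fold falls, cyp520A1, cyp508C1 and cyp513D1 had WT means of only 0.663, 0.573 and 0.140 CPM.

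Some small GTPase genes of the ras and rac families rose from low levels. Of 11 ras genes, 6 were higher and 1 lower, and 5 rose at least 2-fold (adjusted p = 0.00017), among them rasX, from 2.91 CPM ± 0.254 to 6.66 CPM ± 0.916 (SD, n = 4 each), while the abundant rasG was at 794 CPM ± 15.2 and 795 CPM ± 19.1. Of 18 rac genes, 9 were higher and 1 lower, and 5 rose at least 2-fold (adjusted p = 0.0014), and rac1B went from 3.39 CPM ± 0.344 to 44.1 CPM ± 13.1 (SD, n = 4 each); racF1 and racF2 also rose, but are near-identical copies below 5 CPM. Of 8 cpr genes, cysteine proteases, 7 were higher and 3 at least 2-fold (adjusted p = 0.015), and the abundant cprG rose from 3425 CPM ± 186 to 5612 CPM ± 459 (SD, n = 4 each). Of 12 pon genes, named for the membrane protein ponticulin, 6 were higher, 4 of them at least 2-fold (adjusted p = 0.0031), and 2 were lower; ponC4 rose from 2.29 CPM ± 0.176 to 15.4 CPM ± 3.03 (SD, n = 4 each), and the other 3 stayed below 2 CPM. Neighbours of genes almost without counts in the mutant were sometimes lost too: DDB_G0276923_ps beside DDB_G0276925 had a log2 fold change of -6.64, and DDB_G0293164 beside DDB_G0293166 one of -6.05.

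The stretch of 36 tested genes near gtaC was lower almost throughout. Library depth and normalization are argued against. Scaling moves all genes of a library alike, and the median log2 fold change of the other tested genes was 0.0099. The stretch's median was -0.91 with DESeq2 size factors and -0.92 with upper-quartile factors. It stayed between -0.93 and -0.88 in all refits listed for the gene counts. The 50 flanking genes had a median of 0.041. They are no independent test, because the stretch was grown until its outer genes stopped being low. A copy-number difference between the cell lines stays open. Of 7 further genes inside the stretch, too weakly counted to be tested and without part in finding it, 2 had no counts. The other 5 were each lower in the mutant and together had 142 counts in WT, 119 of them in 3 genes, and 69 in the mutant, a log2 ratio of -0.91 (exact binomial 95% interval -1.35 to -0.49, counting error only). Of 10000 random sets of 5 weakly counted genes from elsewhere, with total counts in the same range, 5.93% were as low, so these genes are too few to decide. Silencing of the whole stretch (median -0.91) cannot be told apart from a copy-number difference either, because DNA was not analysed here. Which line departed from the parent strain also stays open.

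The very large rises of transposable-element genes were not a general rise of the class, whose median was -0.12 with 45 of 213 genes higher. Movement of reads between the counted copies is argued against as the whole cause: the total of all 520 transposable-element genes, weakly counted ones included, rose by 253 CPM, from 951 CPM ± 9.62 to 1204 CPM ± 71.7 (SD, n = 4 each; two-sided exact permutation p = 0.029, the smallest possible), although the 481 genes outside the 39 large risers fell by 94.6 CPM together. Of the 38 large risers with a place in the gene order, 28 lay next to another of them, against a mean of 5.88 and at most 16 when as many were drawn at random from the 208 placed genes of the class (permutation p = 0.001 over 1000 draws, the smallest they can give). A difference between the cell lines other than the ttpA change, such as new or altered insertions, cannot be told apart from an effect of the mutation, since the labels name no separate clones.

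What lowered the aggregation genes stays open, and as a set they were not past the threshold with an estimated correlation (adjusted p = 0.128). Mutant cultures growing faster and farther from starvation cannot be told apart from other sources, because lists tied to growth did not agree. All 4 tested discoidin genes, a family with members raised late in growth as cell density rises, were lower in the mutant. The abundant dscE fell from 727 CPM to 510 CPM, and the others are near-identical copies with few counts. Whether dscE itself follows cell density was not tested, and all cultures were frozen at about 80% confluence. Lower discoidin transcripts would go with an earlier stage of growth, but these genes are too few to place the mutant cultures there. Of 35 DNA replication genes, 21 were lower and 0 higher (0 also at an unadjusted edgeR p under 0.05 and with DESeq2), which goes against faster growth. Relative to the replication genes, ribosome biogenesis genes were higher in the mutant by a mean of 0.310 on the log2 CPM scale and tRNA synthetase genes by 0.316 (two-sided exact permutation p = 0.029 for each, the smallest possible). Most of this was the fall of the replication genes (mean log2 fold change -0.215), against mean rises of 0.091 and 0.095. Neither ribosome biogenesis nor tRNA synthetases were past the camera threshold alone. With an estimated correlation camera gave an adjusted p of 0.993 for them and for replication. A lower dose of gtaC (log2 fold change -1.003) acting on the other genes cannot be told apart from an effect of ttpA, because both differences come with the same cell line.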
